A study of Mus musculus with 4 samples.

How the data were processed

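The data came from 4 droplet libraries (10x Chromium, 3′ end) of mouse E14 embryonic stem cells grown on gelatin in medium with fetal serum and LIF: 3 clonal cultures labelled by their LD profile (low, and 2 high) and the culture labelled parental E14. The deposited matrices hold raw UMI counts per gene and barcode, as whole numbers, for 32285 genes and between 1926936 and 2286783 barcodes per library, empty droplets included. Per the submitters' processing notes, reads were aligned and counted with Cell Ranger 6.1.2 on mm10 and analysed with Seurat 4.3.0.1, while the matrix file headers name Cell Ranger 4. No cell list was used from the authors, so cells were called here. Gene positions were taken from the GENCODE M21 annotation of mm10, in which 32158 of the 32285 gene IDs and 10235 of the 10239 tested genes were found.

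A barcode was called a cell when its UMI count reached 10% of the 99th percentile of the 3000 deepest barcodes of its library (5648.6 UMIs in the library labelled parental E14, 6606.8 in the low-LD clone, 6989.9 in high-LD clone 1 and 6992.8 in high-LD clone 2), with at least 1000 genes and at most 15% of UMIs from mitochondrially encoded genes. In the same order 3248, 3116, 4114 and 4277 barcodes reached the UMI minimum and 39, 23, 51 and 39 were lost to the mitochondrial limit. Scrublet (in scanpy, automatic thresholds, 3% doublets expected) marked 3, 0, 0 and 0 cells, which did not separate doublets, so doublets remain. The median mitochondrial share per cell was 3.99, 4.86, 5.28 and 5.86% and the median ribosomal protein share 21.67, 27.25, 25.39 and 24.68%. Where a measure depends on depth per cell, cells were thinned at random to 5000 UMIs. Empty droplets were barcodes with at most 100 UMIs.

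UMIs were summed over the cells of each library and scaled to CPM with edgeR's TMM factors (1.0809, 0.954, 0.955 and 1.0154). Genes with at least 5 CPM in at least 1 library were tested, 10239 in all. Log2 ratios used a pseudocount of 1 CPM. The main rule for a gene was a difference of at least 2-fold, with the same sign in both high-LD clones where these are compared, and is a rule of size without a test. Beside it, edgeR's quasi-likelihood test was run on the 4 sums in 1 fit with 3 groups (high-LD, low-LD, parental), with Benjamini-Hochberg adjusted p under 0.05. Cells were not used as replicates. The p-values measure the spread between the 2 high-LD libraries, which are separate clones, with 1 residual degree of freedom, and the lone libraries are assumed to vary like that pair. The common dispersion was 0.0178 and the prior degrees of freedom were 7.183. The design was tried on simulated data with this dispersion, where 80% of genes with a true 2-fold difference and 100% with a 4-fold difference passed edgeR, 25% and 100% passed the size rule, and 0.14% of unchanged genes passed edgeR. The simulation gave every gene the same dispersion and let the lone libraries vary like the high-LD pair. Its rates are therefore not power or error rates for the real data. DESeq2's Wald test with the same groups was the second tool. The labels give no batch.

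The comparisons, cell rules, lists, named genes and most alternatives were fixed before the data were examined. Named genes are those past the size rule whose symbol is not a Gm number, a Rik or a pseudogene name: the 12 higher and 12 lower with the largest smaller-of-both log2 ratio for high-LD against low-LD, the 6 and 6 for high-LD against parental, the 8 and 8 for low-LD against parental, and the 5 and 5 for the pair of high-LD clones. Also named are 2 to 4 members of each list, and Plin2, Tert, Nanog, Zfp42, Esrrb, Dnmt3b, Fgf5, Otx2, Pou5f1, Sox2 and the Zscan4 genes whatever their values. Genes named because they were the few that passed in a list, stayed under an alternative, lead a cluster or lie near Hprt were chosen after their values were seen.

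There were 33 gene lists: naive, core and formative pluripotency, telomere maintenance, Zscan4 cluster, two-cell-like, lipid droplet, fatty acid synthesis, fatty acid oxidation, cholesterol synthesis, glycolysis, oxidative phosphorylation, mitochondrially encoded, amino acid response (ATF4), p53 targets, S phase, G2M, imprinted, germline, DNA methylation, primitive endoderm, mesendoderm, neuroectoderm, trophoblast, fibroblast, nodal and BMP targets, LIF and WNT targets, immediate early, unfolded protein response, lysosome, hypoxia, antioxidant and Y-linked genes. For the 29 lists with at least 4 tested members, the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile is given. Genes are not replicates, so these percentiles describe the libraries. The number of members past edgeR is given over all genes tested and adjusted over the list alone.

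Chromosome medians used genes with at least 20 CPM in at least 1 library, relative to the median of all such genes. Per cell, the share of autosomal UMIs was taken per chromosome with ribosomal protein genes left out, and a mixture of a pair of normal curves was fitted to cells with at least 10000 UMIs. The line between low and high shares was the crossing point of such a mixture over all libraries. Cells were clustered with code written for this data set and leidenalg (log-normalised counts, 2000 variable genes, 30 components, 15 neighbours, shared-neighbour graph, Leiden resolution 0.5, no integration). Cluster genes were ranked by the log2 ratio of CPM to all other cells with a pseudocount of 5 CPM. The Zscan4 share counted cells with at least 2 UMIs over the cluster after thinning. Y-linked RNA per cell was counted over Ddx3y, Eif2s3y, Kdm5d and Uty, a set chosen after it was seen that Gm47283, which lies at the end of the annotated Y (90784738 to 90816464) in the region shared with X, gave 18585 UMIs even in the library labelled parental E14. The seed was 20240.

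Alternatives tried were median-of-ratios size factors, no CPM filter (at least 10 UMIs in all), a pseudocount of 5 CPM, a minimum of 3000 UMIs per cell, a mitochondrial limit of 10%, doublets kept, cells thinned to 5000 UMIs before summing (shallower cells left out), DESeq2, chromosome genes from 5 CPM, each high-LD clone left out, other Zscan4 minimums and depths, a resolution of 1.0 and clustering without cycle genes. After the data were examined, 5 more were added: cells above 2.5 times the median UMI count left out, the low-depth cluster left out, cells matched for high chromosome 8 and 11 shares, genes of chromosomes 8, 11, 16, Y and M left out, and a fit without the library labelled parental E14. The Zscan4 share without the low-depth cluster was added as well. Free RNA was not subtracted from cells, and DNA variants were not called, as the matrices hold no reads. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, statsmodels 0.14.6 and matplotlib 3.10.9.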

Results

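The data were droplet single-cell RNA counts (10x Chromium, 3′ end) from mouse E14 embryonic stem cells grown in serum and LIF on gelatin. There were 4 libraries: 1 of a clonal culture named for a low LD profile (low-LD clone), 2 of clonal cultures named for a high LD profile (high-LD clones 1 and 2), and 1 of the culture labelled parental E14. The labels do not expand LD. The matrices held 105440646, 101660032, 134980454 and 130753955 UMIs (unique molecular counts) in the library labelled parental E14, the low-LD clone, high-LD clone 1 and high-LD clone 2. In the same order 3206, 3093, 4063 and 4238 barcodes were called as cells, with medians of 19034.5, 20619, 20228 and 20021.5 UMIs and 4708.5, 4755, 4708 and 4799 genes. Summed over cells the libraries held 65083982, 72385685, 93514256 and 96865780 UMIs, and 3 UMIs stood for 0.043, 0.043, 0.034 and 0.03 CPM (UMIs scaled by library size and TMM). Each clone and the parental culture had 1 library, so levels are given without replicate error. Intervals on levels are exact 95% Poisson intervals and cover counting error only.

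The series title places the clones in a study of the exit from naive pluripotency and of a metabolic checkpoint for telomere homeostasis, so the comparison of high-LD with low-LD clones asked which RNAs went with the LD profile. Of 10239 genes tested, 44 were at least 2-fold higher and 43 at least 2-fold lower in both high-LD clones than in the low-LD clone. Between high-LD clones 1 and 2 themselves, 15 genes were at least 2-fold higher and 28 at least 2-fold lower. The edgeR quasi-likelihood test called 22 genes higher and 38 lower, and 21 and 32 of these were also past the 2-fold rule.

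Among the genes higher in the high-LD clones, Usp26 (ENSMUSG00000055780, mm10 chromosome X, 51753959 to 51801233), a testis-enriched deubiquitinase gene, was at 4.42 CPM (3.93 to 4.94) in the low-LD clone, 21.4 (20.5 to 22.4) in high-LD clone 1 and 31.3 (30.2 to 32.4) in high-LD clone 2. It rose 4.85-fold and 7.08-fold with an edgeR adjusted p of 0.0184. Hormad2 (ENSMUSG00000020419, chromosome 11, 4345814 to 4441105), which encodes a protein of meiotic chromosome axes, rose 4.03-fold and 3.67-fold, from 4.16 CPM (3.69 to 4.67) to 16.8 (15.9 to 17.6) and 15.3 (14.5 to 16.1). Stk31, a testis kinase gene, rose 3.69-fold and 3.11-fold, and Fmr1nb, a gene of the testis antigen class, rose 3.29-fold and 2.7-fold. Txnip (ENSMUSG00000038393, chromosome 3, 96557957 to 96561883), whose product restrains glucose uptake and binds thioredoxin, rose 3.31-fold and 2.91-fold, from 10.9 CPM (10.1 to 11.7) to 36.1 (34.9 to 37.4) and 31.6 (30.5 to 32.8). Igsf23, Arl14epl, Ceacam20, Slc1a4 (a neutral amino acid transporter gene) and Runx1t1 also passed edgeR, with folds between 2.8 and 5.38. Zfy1 was 4.42-fold and 6.36-fold higher and Calb2 4.64-fold and 2.83-fold higher, with edgeR adjusted p of 0.0555 and 0.0651. Of the 44 genes, 11 lay on chromosome 11.

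Genes lower in the high-LD clones included 3 small-subunit ribosomal protein genes. Rps29 (ENSMUSG00000034892, chromosome 12, 69157722 to 69159186) fell to 0.302 and 0.288 of its level in the low-LD clone, from 5387 CPM to 1628 and 1551 (edgeR adjusted p 0.0108). Rps27 fell to 0.268 and 0.27 and Rps28 to 0.356 and 0.319 of the low-LD level. These 3 genes were singled out of the ribosomal protein genes by their rank: over all 97 measured ribosomal protein genes the median log2 ratio to the low-LD clone was -0.07 and -0.18 in high-LD clones 1 and 2. A trait of the low-LD library cannot be told from a trait of that clone here, and transcript length was not examined for these genes. Ftl1, which encodes the ferritin light chain that stores iron, fell to 0.226 and 0.265, from 58.6 CPM to 13.3 and 15.6. Hk2 (ENSMUSG00000000628, chromosome 6, 82725025 to 82774454), a hexokinase gene for the first step of glycolysis, fell to 0.363 and 0.367, from 178 CPM (175 to 181) to 64.7 (63 to 66.4) and 65.4 (63.8 to 67), with an edgeR adjusted p of 0.0191. Gfod2 (ENSMUSG00000013150, chromosome 8, 105713854 to 105758664) fell to 0.207 and 0.262, from 79.7 CPM (77.6 to 81.8) to 16.5 (15.7 to 17.4) and 20.9 (20 to 21.8). Efcc1, Ptcra, Dqx1, Atp5k and Snhg9 also passed edgeR, with levels between 0.16 and 0.355 of the low-LD level. Nkx6-3 was at 9.53 CPM in the low-LD clone and at 0.795 and 2.79 in the high-LD clones without passing edgeR (adjusted p 0.123). Of the 43 genes, 8 lay on chromosome 8, which is 18.6% against 5.7% of all genes tested.

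**Figure D1:**
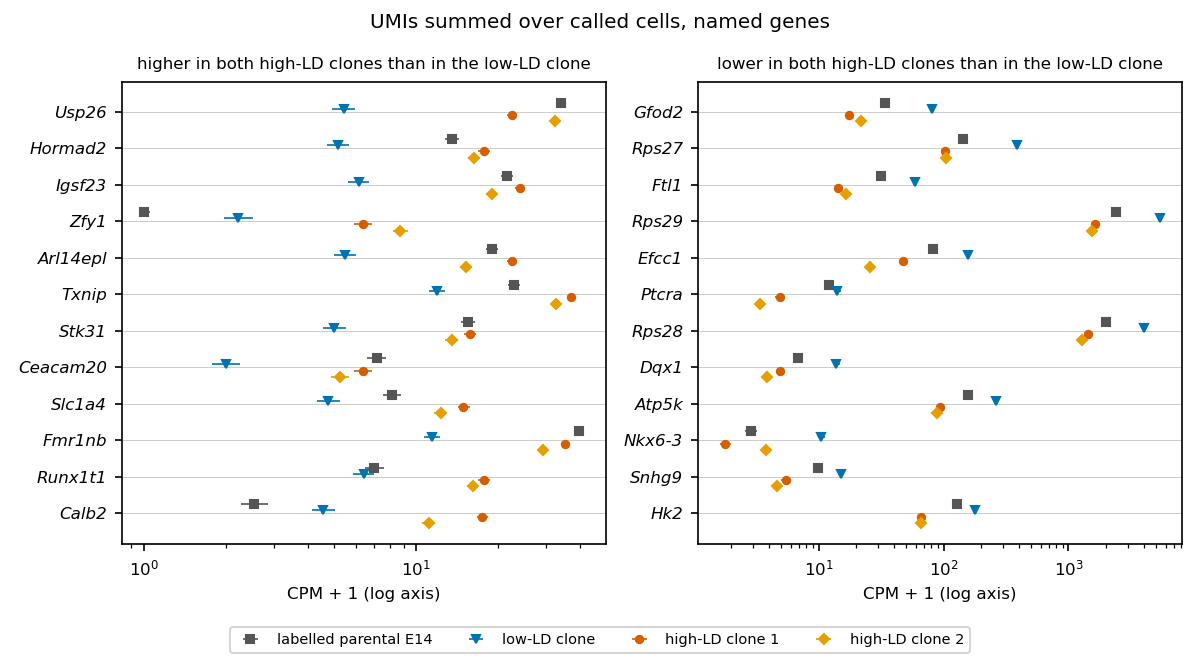
Levels in CPM plus 1 (log axis) of the 12 genes ranked highest among those higher and among those lower in both high-LD clones than in the low-LD clone, 1 point per library, with exact 95% Poisson counting intervals. For Usp26 the library labelled parental E14 (33.1 CPM) sat with the high-LD clones, and Rps29 in the low-LD clone (5387 CPM) lay above the other 3 libraries.

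Pluripotency genes showed no shared direction between the high-LD clones and the low-LD clone. Nanog was at 97.5 CPM in the low-LD clone and at 171 and 105 in the high-LD clones, Zfp42 at 1069, 1069 and 917, Esrrb at 119, 110 and 118, Pou5f1 at 701, 630 and 595, and Sox2 at 435, 508 and 497. The 22 measured genes of the naive list had a median log2 ratio of -0.08, at percentile 10.5 of matched random lists, and the 12 core genes 0.10 (0.2 and 0.01 in high-LD clones 1 and 2, percentile 92.5 for the mean). No member of either list passed edgeR over all genes tested (5 and 1 members at unadjusted p under 0.05, 0 and 0 by DESeq2). Adjusted over the list alone, Dppa3 was higher, at 28.7 CPM against 133 and 70.7, and no core gene passed. The formative list, genes of the state between naive and primed pluripotency, had a median of 0.08 (16 measured) because its members moved apart. Dusp6, a target of ERK signalling, fell from 26.9 CPM to 12.1 and 12.2 over all genes tested. Adjusted over the list alone, 6 members were higher (Dnmt3b, Lef1, Otx2, Pim2, Pou3f1 and Zic2) and 6 lower (Cd24a, Dusp6, Etv4, Lin28b, Spry2 and Spry4). Lef1 was at 2.32 CPM against 10.4 and 5.94, and Spry4 at 61 against 20.1 and 33.4. Fgf5 stayed between 0.896 and 1.48 CPM in the 3 clones.

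Telomere genes were compared because the series title names telomere homeostasis. Tert was at 6.33 CPM (5.75 to 6.95) in the low-LD clone and at 5.44 (4.97 to 5.95) and 6.58 (6.08 to 7.1) in the high-LD clones, with an edgeR adjusted p of 0.942. The 26 measured telomere maintenance genes had a median log2 ratio of -0.02 (percentile 47). None passed edgeR over all genes tested or adjusted over the list alone, with 2 members at unadjusted p under 0.05 and 0 by DESeq2. Atrx was at 385 CPM against 572 and 536, and Nhp2, on chromosome 11, at 594 against 895 and 779. Zscan4d, from a gene cluster tied to telomere lengthening in rare stem cells, was at 0.0579 CPM (0.0158 to 0.148, 4 UMIs) in the low-LD clone and at 0.515 (0.377 to 0.687) and 0.457 (0.334 to 0.612) in the high-LD clones. Zscan4c was at 0.0579, 0.157 and 0.132 CPM, Zscan4b, Zscan4e and Zscan4f had at most 8 UMIs in any library, and Zscan4a was not among the genes of the matrices. After each cell was thinned to 5000 UMIs, at least 2 Zscan4 cluster UMIs were found in 1 of 3093 low-LD cells (0.032%, exact binomial 95% interval 0.001 to 0.18%), 2 of 4063 cells of high-LD clone 1 (0.049%, 0.006 to 0.178%) and 4 of 4238 cells of high-LD clone 2 (0.094%, 0.026 to 0.241%). The share in the library labelled parental E14 was 0.281% (9 of 3206, 0.128 to 0.532%). Without thinning the shares were 0.065, 0.049, 0.094 and 0.405%, at the median depths given above. Single cells carried much of this RNA: 52 of the 62 unthinned Zscan4 cluster UMIs of high-LD clone 1 and 27 of the 71 of high-LD clone 2 came from 1 cell each, so the counting intervals on Zscan4d are too narrow for a comparison of clones. No cell type that should lack these genes was at hand. After thinning, 51 Zscan4 cluster UMIs lay in 10 cells of the library labelled parental E14. High-LD clone 1 had 13 in 3 cells and high-LD clone 2 had 28 in 4 cells. Free RNA would spread over many cells, mostly as single UMIs, so these values argue against it in those libraries. The 4 UMIs in 3 low-LD cells were too few to tell. The difference between high-LD and low-LD clones was not detectable at this depth.

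Lipid genes were compared because the series title names metabolism. The labels do not say whether LD refers to lipids. The 24 measured cholesterol synthesis genes had a median log2 ratio of 0.41 in high-LD clone 1 and 0.31 in high-LD clone 2 (0.32 for their mean, percentile 100), and 19 of the 24 were above 0 in both. No cholesterol gene passed edgeR over all genes tested (8 at unadjusted p under 0.05, 2 higher by DESeq2). The 17 measured fatty acid synthesis genes had medians of 0.25 and 0.37 (0.27 for the mean, percentile 100). Again 0 passed edgeR over all genes tested (8 at unadjusted p under 0.05, 3 higher by DESeq2), and Fasn, Mcat, Scd1, Scd2 and Slc25a1 were higher adjusted over the list alone. Fasn was at 53.6 CPM against 82.5 and 98.8, and Scd2 at 78.3 against 132 and 133. In cells matched for their shares of RNA from chromosomes 8 and 11 the cholesterol median was 0.11 and the fatty acid synthesis median 0.16. Fatty acid oxidation genes (21 measured) had a median of -0.04 (percentile 31) and lipid droplet genes (19 measured) one of 0.02 (percentile 65.8). Neither list had a member past edgeR (3 and 2 at unadjusted p under 0.05, 0 and 1 by DESeq2), and Ldah, a lipid droplet hydrolase gene, was higher adjusted over the list alone, at 8.79 CPM against 17.6 and 17.7. Plin2, a common lipid droplet coat gene, was at 12.2 CPM (11.4 to 13.1), 11.8 (11.1 to 12.6) and 13.3 (12.6 to 14.1).

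Other metabolic, stress and signalling lists were mixed between high-LD and low-LD clones. Glycolysis genes (21 measured) had a median log2 ratio of -0.01 (percentile 54), with Hk2 lower over all genes tested and Aldoc higher adjusted over the list alone. Oxidative phosphorylation genes (32 measured) had a median of -0.08 (percentile 10.1), with no member past edgeR (3 at unadjusted p under 0.05, 0 by DESeq2). The 13 mitochondrially encoded genes had a median of 0.27 (percentile 100), yet mt-Atp8 fell from 266 CPM to 118 and 124 and was the only member to pass. The amino acid response (ATF4) list of 21 genes had medians of 0.29 and 0.15 (0.23 for the mean, percentile 100), with 0 past edgeR (5 at unadjusted p under 0.05, 1 higher by DESeq2) and Stc2 and Trib3 higher adjusted over the list alone. In the antioxidant list (16 measured, median -0.12, percentile 6.6), Ftl1 was lower in both ways of adjusting. The LIF and WNT target list (10 measured) had medians of 0.50 and 0.18 in high-LD clones 1 and 2 (0.34 for the mean, -0.26 to 0.66 over genes, percentile 100), 0.12 in matched cells and 0.08 without the CPM filter, with 0 past edgeR (4 at unadjusted p under 0.05, 0 by DESeq2) and Mycn and Tcf7 (on chromosome 11) higher adjusted over the list alone. In the nodal and BMP target list (12 measured) Id1 fell from 195 CPM to 52.6 and 75.4, Bmp4, Id1 and Id2 were lower and Lefty1, Lefty2 and Smad6 higher adjusted over the list alone, and the median of 0.20 (percentile 98.9) turned to -0.04 without high-LD clone 1. In the germline list (12 measured, medians 0.24 and 0.46, 0.42 for the mean, percentile 100, but -0.08 in matched cells) Stk31 rose over all genes tested, and Stk31, Tex19.1 and Tuba3a were higher adjusted over the list alone. The imprinted list (23 measured) had a median of 0.18 (percentile 99.8) that turned to -0.10 without high-LD clone 2, and no member passed (4 at unadjusted p under 0.05, 0 by DESeq2).

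The remaining lists had no member past edgeR over all genes tested between high-LD and low-LD clones. Adjusted over the list alone, Ccne2 was lower in the S phase list (42 measured, median -0.06), Ckap2 and Hmgb2 lower in the G2M list (52 measured, median 0.03), Egr1 higher and Junb and Jund lower in the immediate early list (11 measured, median -0.10), and Krt19 and Tfap2c higher in the trophoblast list (5 measured, median 0.05). The unadjusted counts of these lists were 3, 3, 4 and 2, and DESeq2 called 0, 3, 2 and 1 members. The p53 target (19 measured, median -0.02), DNA methylation (18, -0.05), unfolded protein response (15, 0.05), lysosome (19, -0.09), hypoxia (12, 0.02), primitive endoderm (6, -0.13), neuroectoderm (7, 0.12) and fibroblast (4, 0.14) lists had none by either way of adjusting, with 3, 1, 1, 3, 2, 3, 1 and 1 members at unadjusted p under 0.05 and 0 by DESeq2. Medians had opposite signs in high-LD clones 1 and 2 for the primitive endoderm (-0.37 and 0.08), neuroectoderm (-0.02 and 0.27), fibroblast (0.19 and -0.24) and trophoblast (0.54 and -0.15) lists. In the lists without a member past edgeR, Pmaip1 was at 6.3 CPM against 3.71 and 3.04, Uhrf2 at 38.9 against 69.4 and 42.2, Pdia4 at 57.8 against 40.6 and 34, and S100a6 at 120 against 84 and 92.6. The two-cell-like list had only Zfp365 and Gm21761 measured (5.23 and 1.45 CPM in the low-LD clone), the mesendoderm and Zscan4 lists had no measured member, and the Y-linked list had Ddx3y, Eif2s3y and Uty, at 30.2, 86.8 and 77.5 CPM in the low-LD clone.

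The edgeR counts for high-LD against low-LD clones were not stable to small changes in scaling or to leaving out the library labelled parental E14. Median-of-ratios factors were 1.0737, 0.957, 0.9542 and 1.0199 for the library labelled parental E14, the low-LD clone and high-LD clones 1 and 2. The TMM factors were close to these, at 1.0809, 0.954, 0.955 and 1.0154. With median-of-ratios size factors, or with that library left out of the fit, edgeR called 0 genes higher and 0 lower (1394 genes at unadjusted p under 0.05 in each, against 1488 with the main scaling). DESeq2 called 127 and 121 and was run only with the library labelled parental E14 in the fit. With median-of-ratios factors the 2-fold rule gave 44 and 43 genes, 43 and 43 of them shared with the main scaling, so it was the p-values and not the 2-fold genes that moved. Of the 44 genes higher by the 2-fold rule, 5 stayed past it, and of the 43 lower genes 23, in cells matched for their shares of RNA from chromosomes 8 and 11: Gm15892, Igsf23, Lrrc75aos2, Myo3b and Txnip, of which Gm15892, Lrrc75aos2 and Myo3b are named here after their values were seen. The germline list median turned to -0.08 in those cells.

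**Figure D2:**
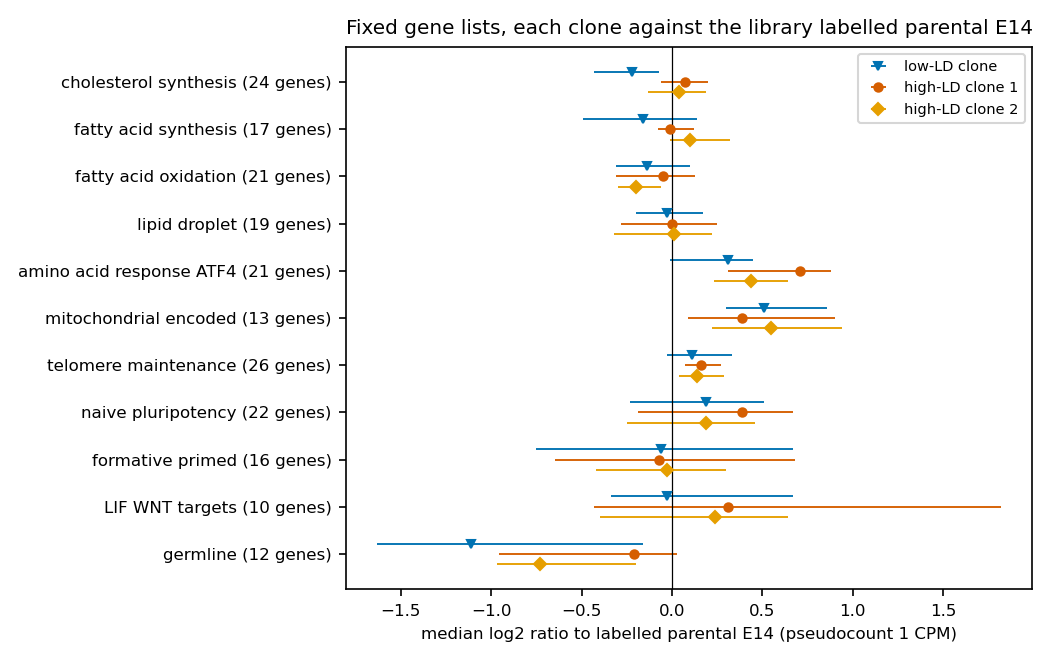
Median log2 ratio (horizontal axis) of 11 fixed gene lists in the low-LD clone and high-LD clones 1 and 2, each against the library labelled parental E14, with order-statistic 95% intervals of the median over genes. The cholesterol synthesis list sat at -0.22 in the low-LD clone and at 0.07 and 0.04 in the high-LD clones.

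The comparison of the high-LD clones with the library labelled parental E14 asked what set these clones apart from the culture they are labelled as coming from. By the 2-fold rule 59 genes were higher and 53 lower in both high-LD clones, and edgeR called 31 higher and 35 lower, of which 30 and 30 were past the 2-fold rule. The genes furthest apart were Hprt and genes of the Y chromosome. Hprt (ENSMUSG00000025630, chromosome X, 52988137 to 53021659), the purine salvage gene used for selection in many stem cell lines, was at 0.185 CPM (0.0984 to 0.316, 13 UMIs) in the library labelled parental E14. It was 694-fold and 533-fold higher in high-LD clones 1 and 2, at 128 CPM (126 to 131) and 98.4 (96.5 to 100), with an edgeR adjusted p of 1.79e-05. Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847) had no UMI in the library labelled parental E14 and was at least 2117-fold and 1859-fold higher, at 90.3 and 79.3 CPM, against a floor of 3 UMIs per library. Uty was 649-fold and 719-fold higher, and Ddx3y was at 0.0284 CPM (0.00344 to 0.103, 2 UMIs) against 52.6 (51.1 to 54.1) and 45 (43.7 to 46.4). Zfy1 was at least 126-fold and 181-fold higher, and Calb2, a calcium-binding protein gene, rose 10.7-fold and 6.52-fold (edgeR adjusted p 0.0183). Among lower genes, Fcrl5 fell from 11.6 CPM (10.9 to 12.5) to 0.403 (0.282 to 0.558) and 0.864 (0.69 to 1.07), Sgcz from 42.2 to 5.64 and 8.79, Aass from 18 to 3.44 and 2.99, and Smtnl1 from 27.5 to 6.8 and 6.97, each past edgeR. Efhc2 was at 8.32 CPM against 0.37 and 1.04 (edgeR adjusted p 0.0361), and Aox3, at 9.34 against 0.425 and 1.91, did not pass (0.0783).

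Of the lists, the amino acid response list had the highest median log2 ratio of the high-LD clones to the library labelled parental E14, at 0.71 and 0.44 (0.60 for the mean, percentile 100), with 18 of 21 members above 0 in both clones. None passed edgeR over all genes tested (14 at unadjusted p under 0.05, 5 higher by DESeq2), and 12 were higher adjusted over the list alone. Of these, Chac1 was at 3.13 CPM against 9.71 and 7.91, Nupr1 at 10 against 33.3 and 18, Trib3 at 7.58 against 15.8 and 13.7, and Atf4 itself at 53 against 91 and 83.4. The naive list had medians of 0.39 and 0.19 (0.36 for the mean, -0.26 to 0.58 over genes, percentile 100), with 0 past edgeR (8 at unadjusted p under 0.05, 3 higher and 1 lower by DESeq2). Adjusted over the list alone, Klf4, Manba, Nr5a2, Prdm14 and Tfcp2l1 were higher and Nr0b1 lower. Tfcp2l1 was at 110 CPM against 360 and 238, and Klf4 at 40.4 against 97.4 and 68.3. The core list had a median of 0.12 (-0.32 to 0.45 over genes, percentile 76.6), with 0 past edgeR (5 at unadjusted p under 0.05, 1 higher and 2 lower by DESeq2), and Dppa5a and Lin28a higher and Dppa2 and Dppa4 lower adjusted over the list alone. Mitochondrially encoded genes had a median of 0.45 (percentile 100), where mt-Nd2 rose from 1566 CPM to 3245 and 3613 and 6 of 13 were higher adjusted over the list alone. Telomere genes had a median of 0.17 (percentile 98), with 0 past edgeR (3 at unadjusted p under 0.05, 1 higher by DESeq2) and Rtel1, a telomere helicase gene, higher adjusted over the list alone, at 24.7 CPM against 42 and 42. LIF and WNT targets had a median of 0.28 (percentile 99.1), with 0 past edgeR (6 at unadjusted p under 0.05, 2 higher by DESeq2), and Axin2, Ccnd1, Mycn and Sp5 higher and Myc and Socs3 lower adjusted over the list alone.

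Other lists were mixed between the high-LD clones and the library labelled parental E14. The germline list had medians of -0.21 and -0.73 in clones 1 and 2 (-0.55 for the mean, percentile 0), Rhox5 fell from 192 CPM to 57 and 76.1, and 5 members were lower adjusted over the list alone (Mov10l1, Rhox5, Rhox6, Rhox9 and Tuba3a). In the antioxidant list (median -0.17, percentile 0.2) Ftl1 and Nqo1 fell, the second from 32.2 CPM to 15.7 and 17.1, and adjusting over the list alone added Hmox1. Id1 and Id2 fell among nodal and BMP targets (median 0.09, with 0.38 and 0.05 in clones 1 and 2), where 4 members were higher and 4 lower adjusted over the list alone. Fatty acid oxidation genes had medians of -0.05 and -0.20 (-0.13 for the mean, percentile 0.7), with Acaa2 and Slc25a20 lower adjusted over the list alone. Lipid droplet genes had a median of 0.02, with Plin2, at 23.4 CPM (22.3 to 24.5) against 11.8 and 13.3, and Plin3 lower adjusted over the list alone. Cholesterol and fatty acid synthesis genes both had a median of 0.04 (percentiles 46.6 and 47) and none passed adjusted over the list alone. Adjusted over the list alone, Hk2 (glycolysis, median -0.04), Peg10 (imprinted, -0.10) and Ndrg1 (hypoxia, -0.06) were lower, and Egr1 (immediate early, 0.03), Nkx6-2 (neuroectoderm, -0.14) and Lamb1 (primitive endoderm, -0.33, with -0.45 and -0.15 in clones 1 and 2) were higher. Cldn6 was higher and Dnmt3a lower in the formative list (median -0.01), Tfap2c higher and Krt18 lower in the trophoblast list (0.02, with -0.27 and -0.23 in high-LD clones 1 and 2), Fn1 higher and Vim lower in the fibroblast list (0.32, with 0.46 and -0.13 in high-LD clones 1 and 2), Herpud1 higher and Sdf2l1 lower in the unfolded protein response list (-0.13, with -0.07 and -0.14 in clones 1 and 2), and Dnmt3a and Dnmt3l lower in the DNA methylation list (0.01). The oxidative phosphorylation (0.03), p53 target (0.12), S phase (0.05), G2M (0.06) and lysosome (-0.05, with -0.3 and -0.05 in clones 1 and 2) lists had no member by either way of adjusting, with 1, 4, 6, 1 and 5 members at unadjusted p under 0.05, and DESeq2 called Pola1 (S phase) higher and Lamp1 (lysosome) lower.

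Over all genes tested, edgeR passed no member of the other lists for which only the list-alone result is given for this comparison. At unadjusted p under 0.05 the fatty acid oxidation, lipid droplet, cholesterol, fatty acid synthesis and glycolysis lists had 4, 3, 1, 2 and 2 members, and DESeq2 called Acaa2, Plin2, Plin3 and Hk2 lower and Ebp and Scd2 higher. The imprinted, hypoxia, immediate early, neuroectoderm and primitive endoderm lists had 8, 6, 3, 2 and 2 members at that level, and DESeq2 called Peg10 and Ndrg1 lower and Nkx6-2 higher. The formative, trophoblast, fibroblast, unfolded protein response and DNA methylation lists had 8, 3, 2, 4 and 7, and DESeq2 called Cldn6 and Fn1 higher and Krt18, Vim and Dnmt3l lower. With median-of-ratios size factors edgeR kept 5 of the 31 higher genes (Ddx3y, Eif2s3y, Hprt, Uty and Zfy1) and 6 of the 35 lower ones, while DESeq2 called 156 higher and 154 lower.

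The low-LD clone was set against the library labelled parental E14 in the same way, with 1 library on each side. By the 2-fold rule 127 genes were higher and 130 lower, 20 of the lower ones on chromosome 11, and edgeR called 29 higher and 41 lower, all past the 2-fold rule. The spread behind these tests came from the high-LD pair. Hprt was at 141 CPM (138 to 144), 763-fold higher, Eif2s3y at 86.8 CPM (84.6 to 89), at least 2034-fold higher, and Uty 605-fold higher. Tenm1, a synaptic adhesion gene, rose 4.54-fold to 18.4 CPM, Csrnp3 3.95-fold to 30.2 and Polr3gl, an RNA polymerase III subunit gene, 3.93-fold to 15.9, while Nkx6-3 was 5.04-fold higher without passing edgeR (adjusted p 0.21). Zfp951 fell from 32.6 CPM (31.3 to 34) to 3.85 (3.4 to 4.34) with an edgeR adjusted p of 0.00119, and Smtnl1 fell to 0.108 and Usp26 to 0.134 of the level in the library labelled parental E14. Fcrl5 fell to 0.0174 and Aass to 0.136 of that level.

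By list, germline genes were lowest in the low-LD clone, with a median log2 ratio of -1.11 (percentile 0) to the library labelled parental E14. Stk31, Rhox5 (192 to 48.4 CPM), Rhox6 (39.3 to 13.7) and Tuba3a (7.95 to 1.07) fell over all genes tested, and 8 of 12 were lower adjusted over the list alone. Cholesterol synthesis genes had a median of -0.22 (percentile 0) with 0 past edgeR (6 at unadjusted p under 0.05, 1 lower by DESeq2). Fatty acid synthesis genes had one of -0.16 (percentile 0.9) with 0 past edgeR (4 at unadjusted p under 0.05, 1 lower by DESeq2) and Slc25a1 lower adjusted over the list alone, at 63 CPM against 35.5. Acadvl fell from 23.6 CPM to 9.8 in the fatty acid oxidation list (median -0.14, percentile 0.7), joined by Acaa2 adjusted over the list alone. Ldah fell from 22.3 CPM to 8.79 in the lipid droplet list (median -0.03), joined by Plin2 and Plin3. Nkx6-2 rose from 5.94 CPM to 20.3 in the neuroectoderm list (median -0.15), where Nes and Tubb3 were lower adjusted over the list alone. Mitochondrially encoded genes had a median of 0.51 (percentile 99.9) with 5 of 13 higher adjusted over the list alone, none past edgeR over all genes tested (8 at unadjusted p under 0.05, 4 by DESeq2). The amino acid response list had one of 0.31 (percentile 99.9) with none by either way (4 at unadjusted p under 0.05, 0 by DESeq2). Ribosomal protein genes had a median of 0.49 (92 of 97 above 0), against 0.32 and 0.24 in high-LD clones 1 and 2, with the same signs under median-of-ratios scaling.

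The remaining lists had no member past edgeR over all genes tested between the low-LD clone and the library labelled parental E14. Adjusted over the list alone, Cldn6, Dusp6, Etv4 and Lin28b were higher and Dnmt3a, Dnmt3b and Pou3f1 lower in the formative list (median -0.06), Bmp4, Nodal and Smad7 higher and Id2 and Smad6 lower among nodal and BMP targets (-0.01), and Tet2 higher and Dnmt3a and Dnmt3b lower in the DNA methylation list (0.05). Ccnd1 (LIF and WNT targets, median -0.03), Pmaip1 (p53 targets, 0.15) and Ftl1 (antioxidant, -0.15) were higher, Krt18 and Krt19 (trophoblast, -0.70) and Sparc (primitive endoderm, 0.00) lower, S100a6 was higher and Vim lower in the fibroblast list (-0.04), and Epas1 was higher and Ndrg1 lower in the hypoxia list (-0.08). The unadjusted counts of these 10 lists, in the order named, were 8, 5, 4, 1, 3, 2, 2, 2, 2 and 4, and DESeq2 called 2, 2, 1, 1, 1, 0, 1, 1, 1 and 0 members. Dnmt3b, for example, was at 69.6 CPM (67.7 to 71.6) against 33.3 (32 to 34.7), and Pmaip1 at 1.51 against 6.3. The naive (0.19), core (0.06), telomere (0.11), glycolysis (-0.06), oxidative phosphorylation (0.08), S phase (0.18), G2M (0.05), imprinted (-0.12), immediate early (0.00), unfolded protein response (-0.18) and lysosome (0.03) lists had none, with 8, 3, 4, 3, 4, 4, 4, 3, 3, 2 and 3 members at unadjusted p under 0.05. DESeq2 called Dppa2 (core) and Sqstm1 (lysosome) lower and Cox6c (oxidative phosphorylation) higher. With median-of-ratios size factors edgeR kept 4 of the 29 higher genes (Ddx3y, Eif2s3y, Hprt and Uty) and 6 of the 41 lower ones.

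All 3 clones were at least 2-fold above the library labelled parental E14 for 30 genes and at least 2-fold below it for 34. The share of genes past the rule in both high-LD clones, times that in the low-LD clone, would give 0.73 and 0.67 genes if the comparisons were independent. These 3 comparisons share the library labelled parental E14, and in 100 simulated draws with a shared library and no true difference the highest count was 0. The draws let the shared library vary only by counting error and the common dispersion of 0.0178, and gave it no trait of its own. At that dispersion the low-LD clone alone had a mean of 1.9 genes past the rule per draw. The draws therefore cannot tell a trait common to the clones from a trait of the library labelled parental E14. The pair of high-LD clones was also compared directly, without a test. Grb10, an imprinted growth regulator gene, was at 17.7 CPM (16.9 to 18.6) in clone 1 and 3.41 (3.05 to 3.79) in clone 2, and H19, an imprinted RNA, at 0.683 (0.522 to 0.877) and 7.73 (7.19 to 8.3). Cdkn1c, also imprinted, was at 46.9 and 13.9 CPM. Sp5, a WNT target, was 4.43-fold, Tagln 7.23-fold and Psors1c2 2.78-fold higher in clone 1, and Col4a1 was at 0.296, Clca3b at 0.244, Aff3 at 0.413 and Acnat1 at 0.238 of its level in clone 2. Of the 28 genes lower in clone 1, 9 lay on chromosome 8 (32.1%).

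Gains and losses of chromosomes are common in cultured embryonic stem cells, so the median log2 ratio per chromosome was taken relative to all genes. Against the library labelled parental E14, the 388 measured genes of chromosome 8 lay at 0.19 (95% interval of the median over genes, 0.15 to 0.22) in the low-LD clone, at -0.31 (-0.35 to -0.28) in high-LD clone 1 and at -0.01 (-0.06 to 0.01) in high-LD clone 2. The 584 genes of chromosome 11 lay at -0.30 (-0.32 to -0.27) in the low-LD clone and at 0.02 and -0.03 in the high-LD clones. Chromosome 16, with 235 genes, lay at -0.34 in all 3 clones. Per cell, the share of autosomal RNA from chromosome 8 fell into a lower and an upper group in the library labelled parental E14 (modes at 4.71 and 6.56%), in high-LD clone 1 (4.41 and 6.07%) and in high-LD clone 2 (4.52 and 6.44%), and into 1 group in the low-LD clone. Above 5.3% lay 68.0% of cells of the library labelled parental E14, 3061 of 3093 low-LD cells, 12.7% of cells of high-LD clone 1 and 65.9% of high-LD clone 2. For chromosome 11, 96.2, 37.3, 95.3 and 84.8% of cells lay above 12.12%, and for chromosome 16, 64.0, 4.7, 2.7 and 3.2% lay above 3.04%. Chromosome 15 fell into a pair of groups in the library labelled parental E14 only (modes at 3.64 and 5.21%, with 9.5% of cells in the upper one). Cells with a high chromosome 8 and a low chromosome 11 share made up 2.8, 61.8, 1.3 and 14.5% of the 4 libraries in the same order. Genes on these chromosomes named above, such as Gfod2, Calb2 and Sgcz on chromosome 8 and Hormad2, Slc1a4 and Tex19.1 on chromosome 11, carry these differences in their values. No test was run on chromosomes.

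**Figure D3:**
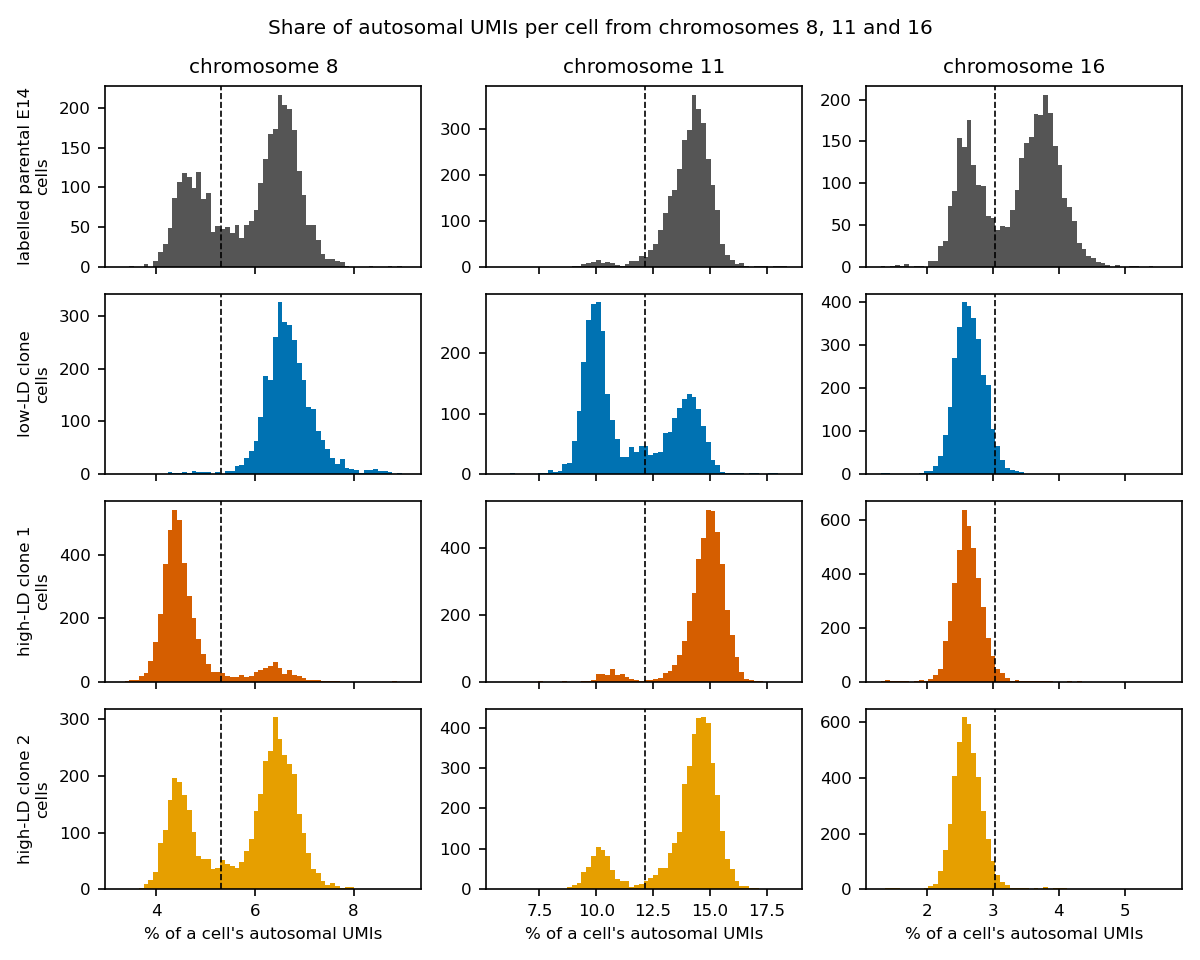
Number of cells by percent of autosomal UMIs from chromosomes 8, 11 and 16 in each of the 4 libraries, with dashed lines at 5.3, 12.12 and 3.04%. The low-LD clone held 3061 of 3093 cells above the line for chromosome 8 and 37.3% above that for chromosome 11.

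Leiden clustering of all cells gave 10 clusters, and 82.3% of cells lay in clusters with at least 80% of their cells from 1 library. Most low-LD cells (77.82%) fell in a cluster led by Rps27, Efcc1, Rps29, Gfod2 and Ftl1. A cluster led by Rora, Dgkb, Nkain2, Tenm1 and Clca3b held 18.49% of low-LD cells and 13.31% of cells of high-LD clone 2, against 2.19% of high-LD clone 1 and 0.47% of the library labelled parental E14. A cluster of 1061 cells held 13.78% of high-LD clone 1 and 10.38% of high-LD clone 2, against 1.2% of low-LD cells and 0.75% of the library labelled parental E14. In it Rhox9 was at 89.6 CPM against 18 elsewhere, Nanos3, a germ cell gene, at 69.9 against 16.7, Tfap2c at 144 against 35 and Dppa3 at 249.4 against 63.1. Without integration most cells clustered by library, so its shares may miss similar cells of other libraries. Clustered alone, the library labelled parental E14 had 567 cells (17.69%) in a cluster with Rhox6 and Rhox9 among its 20 leading genes. The low-LD clone alone had 1017 cells (32.88%) in such a cluster. A cluster of 29 cells had 7 of 9 markers of two-cell-like cells at least 2-fold higher, among them Zscan4c, Zscan4d, Zfp352 and Tcstv3, and held 0.53% of the library labelled parental E14 (17 cells; exact binomial 95% interval 0.31 to 0.85%). It held 4 low-LD cells (0.13%, 0.04 to 0.33%) and 3 and 5 cells of high-LD clones 1 and 2 (0.07%, 0.02 to 0.22%, and 0.12%, 0.04 to 0.28%). A cluster of 171 cells led by Krt18, at 424.8 CPM against 7.6, with Krt8, Tagln and Col4a1 was left unnamed, since 6 of 7 formative and 5 of 8 primitive endoderm markers were at least 2-fold higher. A cluster of 83 cells was led by Hspa1a, Snhg1, Jun and Ddit3. A cluster of 605 cells, 588 of them in the library labelled parental E14, had a median of 7404 UMIs and was led by AY036118, mt-Nd6 and Sgcz. Cluster genes are named by rank within these cells, and cluster shares were not tested between libraries.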

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

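Of the tests in this part, those on scaling, on 2 and 3 chromosome copies and on lipid genes off chromosomes 8, 11 and 16, and those on empty droplets and on cells with Y-linked RNA, were chosen only after the result was seen, as were the cells matched on chromosome shares.

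The chromosome 8 median against the library labelled parental E14 was 0.19 in the low-LD clone and -0.31 and -0.01 in high-LD clones 1 and 2, which drew attention because both high-LD values lay below 0 and the low-LD value above it, with a gap of -0.35; the difference was not tested, and as the interval of clone 2 (-0.06 to 0.01) holds 0, the lower side rests on clone 1. Scaling as the whole cause is argued against because the chromosome 8 median lay at -0.51 between high-LD clone 1 and the low-LD clone relative to all genes, which a common factor cannot move, and it stayed at -0.51 with trends on GC content and transcript length removed. A few strongly changed genes are argued against as well, since all 4 stretches of 97 genes along the chromosome were lower and the one nearest to 0 lay at -0.46. Mixtures of cells with 2 and 3 copies are a candidate explanation: the modes of the chromosome 8 share in high-LD clone 2 stood in a ratio of 1.43. With no compensation 3 to 2 copies would give somewhat less than 1.5, as an added copy also raises the autosomal total. Ratios near 1.43 were seen for chromosome 11 (1.38 in the low-LD clone) and, in the library labelled parental E14, for chromosomes 16 (1.44) and 15 (1.43, 9.5% of cells in the upper mode). No DNA was measured, and whether copy number came with the LD profile or by chance in each clone cannot be read from 3 clones.

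The cholesterol synthesis list lay at -0.22 against the library labelled parental E14 in the low-LD clone and at 0.07 and 0.04 in the high-LD clones, a gap of 0.28 that drew attention because the groups lay on opposite sides of 0, and the difference was not tested. A difference in depth per cell is argued against, as the median between high-LD and low-LD clones stayed at 0.33 after thinning. Dosage of the list's own genes is argued against too, since 0 of its 24 members lie on chromosome 11 and the 22 members off chromosomes 8, 11 and 16 had a median of 0.37 (0.11 to 0.5), while for fatty acid synthesis, with 4 of 17 members on chromosome 11, the members off these chromosomes had a median of 0.15 (-0.13 to 0.61), which decides nothing. An effect of chromosome 11 dosage through other genes and a change of lipid synthesis cannot be told apart: in cells matched for high chromosome 8 and 11 shares the cholesterol median was 0.11 and the fatty acid synthesis median 0.16, against 0.32 and 0.27 in all cells. Matching left 464 cells of high-LD clone 1 and 1149 low-LD cells and also removes any kind of cell that goes with those shares, which keeps the question open, and no other biological explanation was tested.

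Hprt and Y-linked RNA were nearly missing from the library labelled parental E14, while all 3 clones carried both. Cell calling is argued against, because its empty droplets held 0.0 single-copy Y-linked UMIs per 1e+06 UMIs against 132.12, 144.28 and 173.84 in the low-LD clone and high-LD clones 1 and 2. Loss in part of the cells is argued against too, since after thinning 0.06% of its cells had such a UMI against 55.42, 62.86 and 61.87%, and 0.22% had an Hprt UMI against 47.01, 46.07 and 38.15%, at median depths between 19034.5 and 20619 UMIs before thinning; with every gene annotated to Y counted the share was 69.31% against 85.29, 88.46 and 91.74%, and in the library labelled parental E14 Gm47283 alone, in the region shared with X, gave 18585 UMIs against 18 for the single-copy genes. A larger missing segment around Hprt is not borne out either, as its 10 nearest measured genes had a median log2 ratio of -0.2 to the clones (Phf6 was at 22.8 CPM against 39.1, 38.2 and 33.3). What stays open is whether this library is another subline (some E14 sublines lack Hprt by selection), carries a wrong label, or lost both after the clones were taken, none of which was tested, so comparisons with it may carry differences between lines.

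The LIF and WNT target list lay at -0.03 in the low-LD clone and at 0.31 and 0.24 in high-LD clones 1 and 2 against the library labelled parental E14, a gap of 0.31 picked out for its opposite signs and not tested.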

How the results depend on the processing

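Of the alternatives below, those on cells above 2.5 times the median UMI count, the low-depth cluster, matched cells, left-out chromosomes and the fit without the library labelled parental E14 were chosen only after the data were seen. Chromosome medians stayed within their 95% interval over genes in 63 of 63 cases. List medians stayed within theirs, without a change of sign in lists at percentiles up to 2.5 or from 97.5, in 1060 of 1064. These intervals are wide for short lists, and 62 list medians had the other sign than the main value, 18 of them with a high-LD clone left out and 18 in matched cells. Counts within 1.5 times the main count were 60 of 74 by the 2-fold rule and 17 of 68 by edgeR, and shares within their counting interval were 25 of 28 for Zscan4 and 1 of 3 for clusters. Chromosome 8 in high-LD clone 1 ranged from -0.32 to -0.29, chromosome 11 in the low-LD clone from -0.30 to -0.27. Counts are given as higher and lower, and the cause of each change was not tested unless stated. No paired analysis was possible because the labels give no pairing between libraries of the groups.

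By the 2-fold rule, high-LD against low-LD gave 44 and 43 genes. A pseudocount of 5 CPM, which shrinks ratios of weakly expressed genes by construction, gave 10 and 27 there, 22 and 22 for high-LD against the library labelled parental E14, and 53 and 49 for low-LD against it. Leaving out either high-LD clone, so that 1 clone has to pass instead of both, gave 65 to 133 and 59 to 160 for high-LD against low-LD, and 77 to 151 and 71 to 162 for high-LD against the library labelled parental E14. Matched cells gave 5 higher genes for high-LD against low-LD (all among the 44) beside 31 lower (23 among the 43) and 72 higher for low-LD against the library labelled parental E14, leaving out genes of chromosomes 8, 11, 16, Y and M gave 29 of the 44, and no CPM filter gave 217 lower genes for low-LD against the library labelled parental E14, more genes being tested.

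The edgeR counts are given for high-LD against low-LD (22 and 38), high-LD against the library labelled parental E14 (31 and 35) and low-LD against it (29 and 41). A minimum of 3000 UMIs gave 117 and 120, 207 and 164, and 134 and 120, and included the original genes. Thinned cells gave 88 and 107, 149 and 153, and 93 and 103. Median-of-ratios factors gave 0 and 0 in edgeR (1394 genes at unadjusted p under 0.05, DESeq2 127 and 121), 5 and 6, and 4 and 6. No CPM filter gave 235 and 281, 302 and 517, and 229 and 410. DESeq2 gave 127 and 121, 156 and 154, and 105 and 141. Without cells above 2.5 times the median UMI count there were 48 higher, 114 and 103, and 75 and 74. Without the low-depth cluster there were 4 (Hormad2, Igsf23, Txnip and Usp26) and 9, 8 and 13, and 11 and 13. Matched cells gave 47 and 123 (12 and 29 shared), 327 and 329, and 204 and 157. A mitochondrial limit of 10% gave 72 and 67 for high-LD against the library labelled parental E14, and the fit without that library gave 0 and 0 in edgeR for high-LD against low-LD (1394 at unadjusted p under 0.05, DESeq2 with it 127 and 121). With 1 residual degree of freedom, the number of edgeR calls is thus a weak guide.

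For high-LD against low-LD, leaving out either high-LD clone moved the G2M median between -0.04 and 0.11, the imprinted median between -0.10 and 0.08 and the nodal and BMP median between -0.04 and 0.26. Other medians also crossed 0: trophoblast (-0.15 to 0.54), primitive endoderm (-0.37 to 0.08), fibroblast (-0.24 to 0.19), neuroectoderm (-0.02 to 0.27), naive (-0.18 to 0.04), p53 targets (-0.04 to 0.04), telomere (-0.01 to 0.05), glycolysis (-0.06 to 0.01) and lipid droplet (-0.01 to 0.02). Against the library labelled parental E14 these were fibroblast (-0.13 to 0.46), immediate early (-0.11 to 0.07), oxidative phosphorylation (-0.04 to 0.08) and fatty acid synthesis (-0.01 to 0.1). The trophoblast median there, 0.02 for the mean of both clones, turned to between -0.27 and -0.23 with either clone left out. The germline median turned to -0.08 in matched cells. Thinning to 2500 UMIs took the Zscan4 share to 0.125% in the library labelled parental E14 and to 0% in the low-LD clone, as did a minimum of 5 UMIs there (0 of 3093, which allows up to 0.097%); fewer UMIs per cell lower it by construction. The share of cells in clusters from 1 library was 89.5% at resolution 1.0 and 71.6% without cycle genes. In sums, 3 UMIs stand for 0.03 to 0.043 CPM.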

Other observations

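In this part the tests within high-LD clone 2 and on the other leading genes of the Rhox group were chosen only after the result was seen.

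Beyond the comparisons above, the library labelled parental E14 clustered alone held a cluster of 129 cells (4.02%, exact binomial 95% interval 3.37 to 4.76%) with Hormad2, Smc1b, Stra8 and Dmrt1, genes of meiosis and the germ line, among its 20 leading genes beside Fcrl5, Rhox5 and Usp26. A further 13 cells (0.41%, 0.22 to 0.69%) had Gm21761 and Zscan4d, RNAs of the two-cell-like state, among theirs. These genes are named by their rank within the cluster, after their values were seen.

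A group of high-LD cells with Rhox6, Rhox9, Nanos3 and Tfap2c RNA was noticed in the joint clustering and then looked for in the same cells. Each high-LD library clustered alone had 1 cluster with 4 of these 4 genes among its 20 leading genes, 621 cells (15.28%) in clone 1 and 659 cells (15.55%) in clone 2. The library labelled parental E14 (567 cells, 17.69%) and the low-LD clone (1017 cells, 32.88%) each had a cluster with 2 of the 4, Rhox6 and Rhox9. As the 4 genes were picked from a cluster of these cells, the other 16 leading genes found in clone 1 alone were looked up in clone 2 alone, where 9 of them were among the 20 leading genes of 1 cluster and at most 1 of any other, which argues against a difference between clones in every cell. The same count was 7 of 16 in the library labelled parental E14 and 3 in the low-LD clone, there in another cluster than that with Rhox6 and Rhox9, and no biological explanation was tested.

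As a hypothesis from these data, genes higher in the high-LD clones than in the low-LD clone may follow a kind of cell instead of the low-LD library as a whole. Within high-LD clone 2, the 31 such genes off chromosomes 8 and 11 had a median log2 ratio of 1.88 (1.56 to 2.0) between the remaining 3624 cells and the 614 cells with a high chromosome 8 and a low chromosome 11 share, with 31 of 31 in the same direction, against 0.01 over all genes. The genes were chosen partly for high levels in this clone, whose UMIs came mostly from the 3624 cells, so all genes are no fair yardstick. Of the 614 cells, 536 lay in the cluster led by Rora and Dgkb. Among low-LD cells with such shares 524 lay there, but 1330 lay in the cluster led by Rps27, so the 614 cells do not stand for most of them. Usp26 was at 2.42 CPM in the 614 cells and 35.89 in the rest, Fmr1nb at 3.59 and 32.02, and Zfy1 at 0.92 and 8.83. For the 34 genes lower in the high-LD clones the same median was -0.33 (-0.84 to -0.2), with 27 of 34 in the same direction. Of the 34, 10 were at least 2-fold apart in that direction. Clca3b, at 20.04 CPM in the 614 cells against 2.29, and Dusp6, at 27.39 against 10.25, followed the kind of cell. Rps29 (log2 ratio -0.12), Hk2 (-0.17) and Rps28 (-0.23) moved little. Hk2 was at 73.74 CPM in the 614 cells and 65.34 in the rest, against 178 in the low-LD clone, so it did not follow these 614 cells. The lower genes were thus mixed, and their joint median cannot tell the kind of cell from the low-LD library as a whole.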
